A study of Mus musculus with 30 samples.

How the data were processed

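The series holds 30 strand-specific mRNA libraries from mouse white fat, in 6 groups set by sex, cell fraction and genotype label. Per the labels' protocols, minced fat was digested with collagenase at 500 U/ml, for 20 min (epididymal) or 30 min (posterior subcutaneous), passed through a 300 µm strainer and spun at 80 g for 8 min, which leaves adipocytes floating above the stromal-vascular cells (SVC). The labels name both depots for every library, do not name the driver of the deletion or the exons it removes, and give replicate numbers but do not state that each number is a separate mouse. P-values therefore measure the spread between these libraries.

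The authors deposited a table of raw read counts per gene and a table of log2 values. Per the submitters' processing notes, FastQC 0.12.1, STAR 2.7.11a, DESeq2 and the genome build mm39 were used, and the counting program, its strand setting and the annotation are not given in the sources used here. The deposited counts were whole numbers with total counts of 20484836 to 22209603 per library, over 35120 genes, of which 33501 carried a symbol. The authors' log2 values were regularised logarithms (rlog) made with DESeq2, per the file headers, and ranged from -2.36 to 29.3. They were used only as a check on direction, because they are shrunken and no longer counts. No per-sample column was left unused (0 other columns), and no pair of libraries within a group differed by so little as counting noise (the lowest chi-square per degree of freedom was 12.9).

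Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter (minimum count 10) and robust dispersion estimates. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and a gene was called below 0.05. The 23 adipocyte libraries were fitted together as 4 groups, which gave the male and female genotype comparisons, the difference between them and the comparison of female with male controls. The 7 SVC libraries were fitted alone. The 18 male libraries were fitted together for the comparison of fractions and for the difference of the genotype effects between fractions. Levels quoted as group means are means of CPM (counts scaled to the library total) adjusted by TMM within that fit, with the standard deviation (SD) between libraries. Levels quoted per library or as ranges, and those of Ctnnb1, Xist and Ddx3y, are CPM of the library total. Fold changes are on the log2 scale with their standard errors (SE). CPM has no correction for gene length, and reads shared between near-identical copies, such as ribosomal protein genes and their pseudogenes, immunoglobulin segments or mitochondrial genes and their nuclear copies, may be split by the authors' counting.

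Fixed gene lists, 31 in number, covered pathways of fat cells, Wnt signalling and markers of other cell types. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, which asks whether the members of a list move one way. Lists with fewer than 3 measured genes were left out, which left 30 lists in adipocyte comparisons. Counts within a list are given over all genes tested and adjusted over the list alone. List indices are means of log2 CPM over the members in a library. They were compared by exact two-sided permutation, or by 100000 permutations where both sexes were combined. For 3 lists the t statistic of the index was also compared with the largest of all 30 lists in each split or in 10000 permutations, which allows for the choice of the list.

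The rule for named genes was written before the data were examined. It took Ctnnb1, then the 8 called genes of largest log2 fold change each way (6 each way between sexes and fractions, and 5 in a difference of effects). These needed a mean of at least 1 CPM in 1 of the groups and every library of 1 genotype beyond the mean of the other, and predicted genes and pseudogenes were left out. With no called gene it took the 3 of smallest p each way, and from each list up to 3 called members or the member of smallest p. Xist, Ddx3y, Upk3b, Msln, Fmo4, Pank1, Ucp1, the mitochondrially encoded genes, the epididymal and sperm transcripts, and the genes described around Rpl29 and Adipoq fall outside it and were chosen after their values were seen. Of the genes this rule names, 1 is not reported here. The tables, alternatives and lists were also fixed before the data were examined. The alternatives were other scalings and filters, DESeq2 1.42.0, limma-voom, other sets of libraries in the fit, replicate blocks, cell type or depot indices as covariates and leaving out each library in turn. Fits without libraries that stood apart, and an average of the genotype effect over both sexes, were added after seeing the data.

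The procedure was tested on simulated counts drawn from the real means and library sizes. In the male adipocyte comparison, run on 14074 genes, edgeR recovered 38.8% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 100% of those changed 4-fold. In the female comparison the shares were 55.2%, 79.1% and 97.0%. In the SVC comparison, run on 16111 genes, they were 0%, 0% and 12.1%, and 66.2% of the genes DESeq2 called there were false, so the SVC test misses most changes up to 4-fold. Annotation from GENCODE M21 was used for gene types, chromosome numbers and the order of neighbouring genes. It belongs to an earlier genome build than the authors', so no coordinates are printed.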

Results

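The study asked what loss of β-catenin in fat cells does to adipose tissue. β-catenin, encoded by Ctnnb1, carries the canonical Wnt signal into the nucleus and also links cadherins to the cytoskeleton at cell junctions. The RNA libraries are labelled as adipocyte-specific knockout (Ctnnb1AdKO) or as sex- and age-matched Ctnnb1fl/fl control. There were 6 adipocyte libraries of male controls, 5 of male knockouts, 6 of female controls and 6 of female knockouts. Of stromal-vascular cells (SVC), a mixture of preadipocytes, immune, endothelial and other cells, there were 3 libraries of male controls and 4 of male knockouts. Total counts lay between 20484836 and 22209603 per library, so depth differed little between groups.

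Ctnnb1 mRNA was not lower in the libraries labelled knockout. In male adipocytes it averaged 328 ± 23.2 CPM (SD, n = 5) in libraries labelled knockout and 326 ± 11.7 CPM (n = 6) in controls, in female adipocytes 329 ± 30.5 against 320 ± 22.6 CPM (n = 6 each), and in SVC 530 ± 164 (n = 4) against 513 ± 61.8 CPM (n = 3). Exact two-sided permutation tests gave p = 0.913, 0.604 and 1. The log2 fold changes were -0.03 (SE 0.08, adjusted p = 0.919) in males, 0.11 (SE 0.07, adjusted p = 0.670) in females and 0.08 (SE 0.25, adjusted p = 0.979) in SVC. A count over the whole gene need not fall when only some exons are removed, and the removed exons are not named. The genotype labels are therefore not checked by this gene, and knockout below stands for the libraries labelled so. The labels of sex were borne out: Xist averaged 104 CPM in female controls and 118 CPM in female knockouts and stayed at or below 0.326 CPM in all male libraries, and Ddx3y counted 0 in all 12 female libraries.

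**Figure D1:**
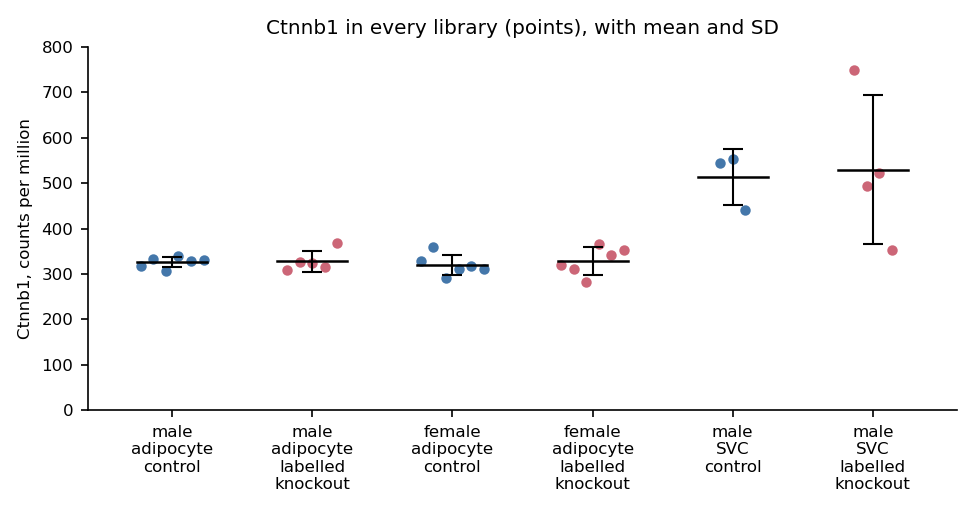
Ctnnb1 in CPM (vertical axis) in each of the 30 libraries (points), by group, with the mean and SD of each group in black. The means of libraries labelled knockout and of controls differ by less than the SD within each pair of groups, for example 328 against 326 in male adipocytes.

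In male adipocytes, knockout libraries had less mRNA of Pon1 and of 2 serpin genes and more of Bicd2. Pon1, which encodes the lipoprotein-bound esterase paraoxonase, fell by 2.95 on the log2 scale (SE 0.38, adjusted p = 0.000876), from 13.7 ± 5.28 to 1.77 ± 0.633 CPM. The serine protease inhibitor genes Serpina3b and Serpina3k fell from 23.4 ± 9.58 to 4.71 ± 1.30 CPM and from 7.68 ± 1.15 to 2.65 ± 0.510 CPM (log2 -2.31 and -1.53, adjusted p = 0.00377 and 0.00211). They belong to a cluster of near-identical genes, so reads may be split among them. Bicd2, an adaptor that ties cargo to the dynein motor, rose from 44.7 ± 6.19 to 67.8 ± 7.54 CPM (log2 0.60, adjusted p = 0.00438). All 5 knockout libraries lay beyond the control mean in each of these, a separation that the naming rule asked for in 1 genotype.

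In total 10 of 14227 genes were called in males, 3 higher and 7 lower, and 1861 had an unadjusted p below 0.05 where 711 are expected by chance. The other higher genes were Btbd10 (log2 0.48, adjusted p = 0.0365) and Morf4l2, a chromatin factor (log2 0.45, adjusted p = 0.0192). The other lower genes were Colec12, a scavenger receptor (25.3 ± 4.77 to 14.0 ± 3.80 CPM, log2 -0.85, adjusted p = 0.0296), and Bckdhb, a subunit of the enzyme that breaks down branched-chain keto acids (223 ± 24.4 to 148 ± 26.1 CPM, log2 -0.59, adjusted p = 0.0365). So were the homeobox gene Hoxc10 (0.577 to 0.133 CPM, log2 -2.08, adjusted p = 0.0192) and the flavin monooxygenase gene Fmo4 (0.953 to 0.311 CPM, log2 -1.60, adjusted p = 0.0192), the last 2 near the limit of detection. Of the 30 lists only the mesothelial markers were called with all libraries. Without knockout 5 the lipogenesis (adjusted p = 0.00293) and oxidative phosphorylation (0.000143) lists were called lower and the sex-linked list higher (0.00473), and without control 6 the erythroid list (0.0427), so the count ran from 1 to 4. All 13 measured mesothelial markers had negative fold changes, with a median of -1.46. They had none called over all genes and 8 lower when adjusted over the list alone (camera adjusted p = 2.48e-05; adjusted p = 0.932 with an estimated correlation). Mesothelial cells cover the surface of visceral fat, and their transcripts were few here: Upk3b averaged 22.4 ± 18.3 CPM in controls and 6.85 ± 4.09 CPM in knockouts. The Wnt target list had a median of 0.09 and no called member (camera adjusted p = 0.825).

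Several metabolic and immune genes had sizeable estimates in males that missed the threshold. They include Grb14, an adaptor that restrains the insulin receptor (log2 0.78, adjusted p = 0.0795), Hsd17b7 of cholesterol synthesis (0.82, adjusted p = 0.0945), the clock gene Arntl (1.17, adjusted p = 0.0700) and the respiratory chain gene Atp5o (-0.72, adjusted p = 0.0723). Others were Lep (0.54, adjusted p = 0.283), the macrophage genes Gpnmb (1.49, adjusted p = 0.121) and Mmp12 (1.61, adjusted p = 0.147), and the mesothelial gene Muc16 (-1.92, adjusted p = 0.156). Male knockout 5 weighed on these results: without it 332 genes were called, Grb14, Gpnmb, Arntl and Atp5o among them (adjusted p = 0.0205, 0.0296, 0.0408 and 0.0131). Grb14, Gpnmb and Atp5o were also called without control 6 (0.0437, 0.0332 and 0.0437), and Arntl without control 2 or knockout 3 (0.0396 and 0.0161). The count was 55 without control 2, 4 without control 1 and 6 without knockout 4. DESeq2 called 159 genes, and upper-quartile scaling gave 1 higher and 8 lower.

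Pon1, Serpina3b, Serpina3k and Bicd2 stayed below 0.05 with any 1 of the 11 male libraries left out. Over all 26 alternatives only Serpina3b among them kept its call throughout. Pon1 and Serpina3k lost it in 1 each and Bicd2 in 4 (highest adjusted p = 0.0926, 0.240 and 0.235). The other calls depended on single libraries. Btbd10 lost its call without control 1, 3, 4, 5 or 6 or knockout 1, 2 or 4 (adjusted p = 0.0504 to 0.156). Bckdhb lost it without control 1, 4 or 6 or knockout 1, 2, 3 or 4 (0.0511 to 0.131). Morf4l2 lost it without control 1, 3 or 4 or knockout 4 (0.0583 to 0.0864), and Colec12 without control 1 or 5 or knockout 1 or 3 (0.0504 to 0.118). Hoxc10 and Fmo4 lost it without control 1 or knockout 1 or 4 (0.0581 to 0.0819 and 0.0539 to 0.0710).

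In female adipocytes, knockout libraries had more mRNA of Cidea, Otop1, Ppargc1a and Grb14 and less of C1qc. Cidea, a lipid droplet protein abundant in brown fat, rose from 20.4 ± 10.6 to 82.2 ± 15.3 CPM (log2 2.01, SE 0.44, adjusted p = 0.0364), and Otop1, a proton channel enriched in brown fat, from 2.77 ± 1.98 to 11.8 ± 2.98 CPM (log2 2.09, adjusted p = 0.0409). Ppargc1a, a coactivator of mitochondrial biogenesis, rose from 2.77 ± 1.29 to 6.46 ± 2.17 CPM (log2 1.22, adjusted p = 0.0143). The complement gene C1qc fell from 40.6 ± 12.9 to 17.8 ± 6.59 CPM (log2 -1.19, adjusted p = 0.0376). The most firmly called gene was Grb14, which rose from 6.51 ± 1.83 to 19.1 ± 1.99 CPM (log2 1.55, SE 0.18, adjusted p = 0.000126). All 6 knockout libraries lay beyond the control mean in each of these 5 genes. The naming rule asked for such a separation in genes of largest change, so for those it is not separate evidence.

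**Figure D2:**
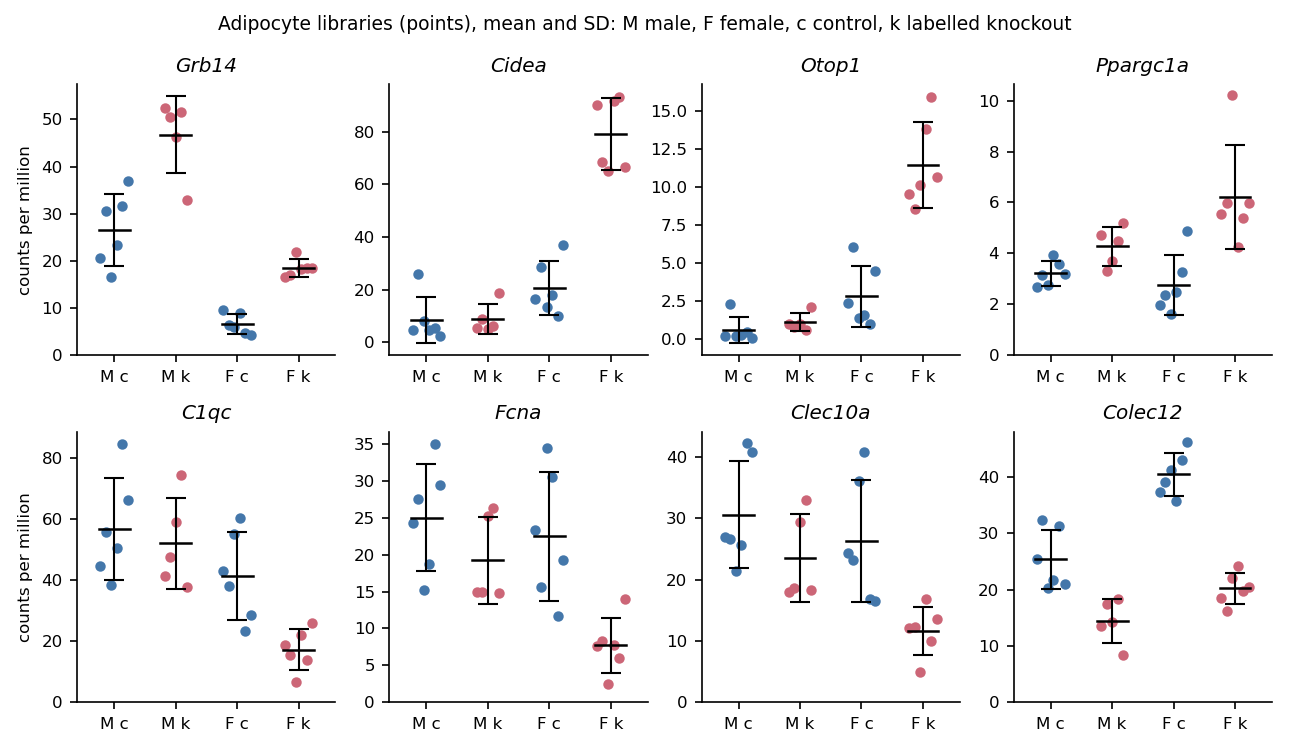
CPM (vertical axes) of 8 genes in the adipocyte libraries (points) of male controls, male knockouts, female controls and female knockouts, with the mean and SD of each group. Cidea and Otop1 are higher in every female knockout library than in any female control library, and the males show no such separation.

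In all, 67 genes were called in females, 46 higher and 21 lower, and 1469 had an unadjusted p below 0.05 where 711 are expected. The thermogenic list had the smallest camera p: 4 of 15 measured members were called higher (Otop1, Cidea, Ppargc1a and Pank1, the last with log2 0.92 and adjusted p = 0.0472). On this list 11 were higher when adjusted over the list alone, and the median was 1.07 (camera adjusted p = 2.67e-18, adjusted p = 0.00638 with an estimated correlation, fry adjusted p = 0.000193). Ucp1, the uncoupling protein of brown fat, averaged 79.7 ± 43.8 against 21.4 ± 27.8 CPM but was not called (log2 1.90, SE 1.02, adjusted p = 0.541). Its control mean rested largely on control 6 (72.4 CPM, the others at or below 28.7 CPM; log2 2.90 and adjusted p = 0.337 without it). Limma-voom called it (log2 2.56, adjusted p = 0.0496), and with the depot index as a covariate its log2 fold change was 0.41 (adjusted p = 0.859). Transcripts encoded by mitochondrial DNA took up 6.87 ± 0.824% of counts in knockouts and 4.37 ± 0.601% in controls, with no overlap (lowest knockout 5.92%, highest control 5.19%, exact permutation p = 0.00216, n = 6 each). Of 12 measured mitochondrially encoded protein genes 7 were called higher, and all 12 had positive fold changes with a median of 0.73. In males this share was 2.28 ± 0.561% against 1.83 ± 0.149% (exact permutation p = 0.0996, n = 5 and 6), and none of the 12 genes was called.

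Among macrophage and monocyte markers in females, 18 of 19 had negative fold changes with a median of -0.88. Of these 1 was called over all genes (C1qc) and 13 were lower when adjusted over the list alone (camera adjusted p = 1.09e-13; adjusted p = 0.241 with an estimated correlation). Also called lower, outside the list, were the lectin genes Clec10a (25.7 ± 8.99 to 11.9 ± 3.73 CPM, log2 -1.11, adjusted p = 0.0472), Cd209d (log2 -1.12, adjusted p = 0.0488) and Fcna (22.0 ± 8.17 to 7.94 ± 3.76 CPM, log2 -1.47, adjusted p = 0.0240), and Pld4 (log2 -1.03, adjusted p = 0.0458). Mesothelial markers had a median of -1.57, with 10 of 13 lower when adjusted over the list alone (camera adjusted p = 6.90e-07; adjusted p = 0.286 with an estimated correlation). Their member of smallest p was Krt7, at 0.471 against 4.96 CPM (log2 -3.37, adjusted p = 0.0569). Its control mean rested largely on control 4 (22.2 CPM, the others at or below 4.66 CPM; log2 -1.90 and adjusted p = 0.297 without it), and it was called without control 1, 2 or 5 (adjusted p = 0.0459, 0.0390 and 0.0313). Control 4 also had the highest index of mammary and skin epithelial markers among the female libraries (2.15), followed by control 6 (1.18). Whether Krt7 there came from mesothelial or other epithelial cells was not tested.

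The remaining called genes of large change included Gnal, the G protein subunit that couples receptors to adenylyl cyclase in olfactory neurons (0.552 to 3.82 CPM, log2 2.78, adjusted p = 0.00611), Vat1l (log2 1.89, adjusted p = 0.000425), the matrix genes Comp and Col27a1 (log2 2.61 and 1.81, adjusted p = 0.0306 and 0.00382) and the ribosomal protein gene Rpl29 (27.4 ± 4.63 to 95.2 ± 37.6 CPM, log2 1.80, adjusted p = 0.00846, 5 of 6 libraries). Igfbp2, a carrier of insulin-like growth factors, fell by 4.80 (adjusted p = 0.0386), from 1.73 ± 2.65 to 0.0576 ± 0.0592 CPM, and its control mean rested largely on control 4 (7.32 CPM; adjusted p = 0.144 without it). Colec12 (40.1 ± 5.66 to 20.9 ± 2.24 CPM, log2 -0.94, adjusted p = 0.00382) and Plxdc2 (log2 -0.92, adjusted p = 0.0208) were also lower.

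Camera called 15 of 30 lists in females, and only the thermogenic list held with an estimated correlation. Lists of lipid handling were higher: de novo lipogenesis (median 0.55, 22 of 25 positive, camera adjusted p = 1.59e-06), cholesterol synthesis (0.47, 1.32e-06), oxidative phosphorylation (0.21, 1.32e-06) and lipolysis with fatty acid oxidation (0.19, 4.54e-05), with adjusted p = 0.421, 0.421, 0.421 and 0.256 with an estimated correlation. Their members of smallest p included the desaturase Scd1 (log2 0.87, adjusted p = 0.0613) and Hadhb of mitochondrial β-oxidation (log2 0.41, adjusted p = 0.0505). Scd1 was called without control 5 or knockout 3, 4 or 6 (0.0434, 0.0382, 0.0353 and 0.0413), and Hadhb without knockout 3 (0.0346). The interferon list was higher (median 0.37, camera adjusted p = 6.90e-07; adjusted p = 0.269 with an estimated correlation), as was the cell cycle list (0.29, 0.0139; adjusted p = 0.492 with an estimated correlation). Other lists were lower. They were Wnt targets (median -0.21, 0.00390; adjusted p = 0.241 with an estimated correlation), with the feedback gene Axin2 at log2 -0.81 (adjusted p = 0.162), and Wnt ligands and receptors (-0.11, 0.0174; adjusted p = 0.421), with the co-receptor Ryk at -0.42 (adjusted p = 0.0521). Also lower were immediate-early stress genes (-0.22, 3.61e-05; adjusted p = 0.160), unfolded protein response and hypoxia (-0.23, 0.000222; adjusted p = 0.256), inflammatory cytokines (-0.41, 0.00192; adjusted p = 0.450) and erythroid markers (-0.57, 0.0447; adjusted p = 0.529, each with an estimated correlation). Jund (log2 -0.51, adjusted p = 0.0521) and Atf4 (log2 -0.36, adjusted p = 0.0881) led the stress lists and Cd274 (log2 0.68, adjusted p = 0.144) the interferon list, none of them called with all libraries. Jund was called without control 2 or knockout 6 (0.0234 and 0.0330) and Atf4 without control 2 (0.0363). The Wnt target and inflammatory lists lost their calls without knockout 3 (adjusted p = 0.0553 and 0.201). So did the Wnt ligand list without control 3 or knockout 5 (0.0538 and 0.0882), the cell cycle list without control 5, control 6 or knockout 4 (0.207, 0.171 and 0.307) and the erythroid list without control 1, 3 or 4 or knockout 3, 5 or 6 (0.0553 to 0.365). Other lists gained a call. They were preadipocyte markers without control 5 or 6 or knockout 1 or 4 (0.0155 to 0.0461), granulocyte markers without control 5 or 6 or knockout 4 (0.0352 to 0.0407), endothelial markers without control 3 or knockout 3 or 5 (0.0169 to 0.0381), matrix genes without knockout 5 (0.0312) and sex-linked genes without control 6 (0.0463).

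The number of called genes in females depended on single libraries and settings. It fell to 33 without control 3, 39 without control 4, 32 without knockout 1, 42 without knockout 2 and 40 without knockout 5. It fell to 26 with the 2 groups fitted alone and to 20 with the macrophage index as a covariate, while DESeq2 called 206 (100 higher, 106 lower). Grb14, Gnal, Vat1l, Col27a1, Rpl29, Ppargc1a and Colec12 kept their calls with any 1 of the 12 libraries left out. Over all 26 alternatives Grb14, Vat1l and Colec12 kept theirs throughout. Ppargc1a lost its call in 5, Col27a1 and Rpl29 in 2 each and Gnal in 1 (highest adjusted p = 0.253, 0.0617, 0.0756 and 0.0682). Cidea lost its call without control 1, 3, 4 or 5 or knockout 1, 2, 4 or 5 (adjusted p = 0.0530 to 0.107). Otop1 lost it without the same libraries or knockout 3 (0.0521 to 0.121), and Pank1 without control 1, 2, 3 or 4 or knockout 1, 2 or 5 (0.0765 to 0.142). C1qc lost it without control 1, 3 or 4 or knockout 1 to 5 (0.0530 to 0.132), Cd209d without control 1 to 4 or knockout 1 to 5 (0.0583 to 0.164) and Clec10a without control 1 to 4 or knockout 1, 2, 3, 5 or 6 (0.0527 to 0.174). Pld4 lost it without control 1, 2, 3, 4 or 6 or knockout 1 to 5 (0.0557 to 0.144), and Fcna without control 3 or 4 or knockout 1, 2, 4 or 5 (0.0530 to 0.0839). Comp lost it without control 1, 2, 3, 5 or 6 or knockout 3 (0.0583 to 0.0801), Plxdc2 without control 3 or 6 or knockout 1, 2 or 3 (0.0517 to 0.0680) and Igfbp2 without control 4 or 6 or any knockout (0.0613 to 0.144).

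**Figure D3:**
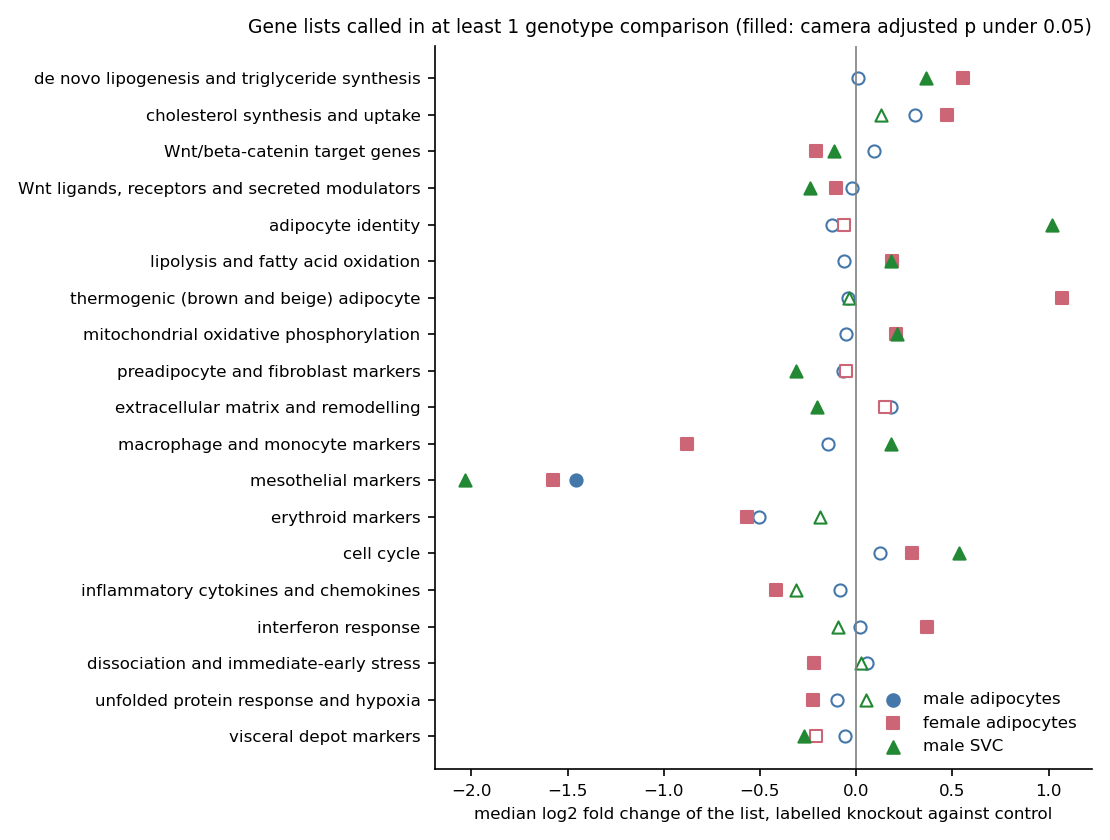
Median log2 fold change (horizontal axis) of each gene list called in at least 1 genotype comparison (vertical axis), for male adipocytes, female adipocytes and male SVC, with filled symbols where the camera adjusted p at the preset correlation was below 0.05. The mesothelial list is the one called in all 3, with medians of -1.46, -1.57 and -2.03.

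Across the 14227 genes the knockout effects in males and females were weakly related (Pearson r = 0.248; 0.133 without male knockout 5 and 0.160 without female knockout 4), and genes are not independent replicates. Of the 67 genes called in females 58 had the same sign in males, and of the 10 called in males 6 had the same sign in females, where 56.5% of all genes did. Colec12 was the 1 gene called in both, where 0.0471 are expected of independent lists. The effects differed significantly between the sexes for 2 genes. Sex, depot and batch cannot be separated here from the labels, which do not assign depots to libraries. With an index of subcutaneous against visceral markers as a covariate both calls were lost. Serpina3k fell in males but stood at 1.58 ± 0.508 CPM in female knockouts and 1.13 ± 0.418 CPM in female controls (log2 difference, female minus male, 2.01, adjusted p = 0.0213). Akirin2, a nuclear factor of innate immune transcription, averaged 31.8 ± 1.24 against 37.4 ± 1.04 CPM in females and 35.6 ± 2.39 against 28.3 ± 2.39 CPM in males (log2 difference -0.57, adjusted p = 0.0299). By camera 10 lists differed, and none with an estimated correlation (lowest adjusted p = 0.341). The thermogenic (median difference 1.22, camera adjusted p = 1.96e-06), lipogenesis (0.41, 5.15e-06), oxidative phosphorylation (0.20, 3.99e-06), lipolysis (0.25, 3.50e-05), interferon (0.42, 5.72e-05) and cholesterol (0.16, 0.0493) lists had a more positive effect in females than in males. The macrophage (-0.86, 1.96e-10), immediate-early stress (-0.27, 0.00171), unfolded protein response (-0.18, 0.0104) and Wnt target (-0.22, 0.0293) lists had a more negative one. These counts moved with single libraries. They were 22 without male knockout 5, 4 without male control 2 and 0 without male knockouts 1 or 2 or female controls 5 or 6, where Serpina3k lost its call (adjusted p = 0.0578 to 0.0770). Only Serpina3k was left without male knockout 4, female controls 3 or 4 or female knockouts 1, 3, 4 or 6. Akirin2 lost its call in all of these cases (0.0508 to 0.0858). The cholesterol list lost its call without male control 1, 3, 4, 5 or 6, male knockout 1 to 4, female control 3, 4 or 6 or female knockout 1, 2 or 4 (0.0533 to 0.325). The Wnt target list lost it without male control 3 or 6, male knockout 1 or 3, female control 1 or female knockout 3 or 5 (0.0505 to 0.0655, and higher without female knockout 3), and the unfolded protein list without female control 6 (0.0755). Lists that gained a call were insulin signalling without female control 5 or 6 or female knockout 3 or 4 (0.0251 to 0.0390), endothelial markers without male knockout 5 (0.0300), inflammatory cytokines without male control 5 or female knockout 4 or 6 (0.0184 to 0.0488) and subcutaneous markers without male control 4 (0.0447) or, just under 0.05, female knockout 2.

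In the male SVC no gene differed significantly between knockout and control. Of 16404 genes edgeR called 0, and 429 had an unadjusted p below 0.05 where 820 are expected. Limma-voom called 0, DESeq2 76 and edgeR with all 30 libraries in the fit 19. The genes of smallest p were all lower: Wnt2b (19.5 ± 7.63 to 3.82 ± 0.106 CPM, log2 -2.35) and the immunoglobulin segments Ighv1-72 (-2.94) and Igkv8-19 (-4.92), with adjusted p = 0.465 each. Genes with higher estimates were further from a call, among them Cdk18 (log2 1.52), Stra6l (1.62) and Gpnmb, a lysosomal macrophage protein (143 ± 34.1 to 429 ± 169 CPM, 1.58), with adjusted p = 0.968 each. Spread between these libraries was large (n = 4 and 3), and leaving out control 3 gave 1 called gene.

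Camera called 12 of 31 lists in SVC and none with an estimated correlation. Mesothelial markers had a median of -2.03 with 13 of 14 members negative and 9 lower when adjusted over the list alone (camera adjusted p = 3.91e-17; adjusted p = 0.200 with an estimated correlation). Upk3b averaged 173 ± 98.1 CPM in controls and 27.4 ± 8.55 CPM in knockouts, Msln 44.9 ± 26.4 and 8.33 ± 3.07 CPM, and Upk1b 35.0 ± 18.3 and 4.72 ± 0.928 CPM (log2 -2.89, adjusted p = 0.511). The visceral depot list, which shares Bnc1 (log2 -2.33, adjusted p = 0.968) and Wt1 with the mesothelial list, had a median of -0.27 (camera adjusted p = 0.000309; adjusted p = 0.423 with an estimated correlation). Preadipocyte markers were lower (median -0.31, 19 of 20 negative, camera adjusted p = 2.22e-07), with F3 at -0.58. So were Wnt ligands and receptors (-0.24, 8.98e-06), matrix genes (-0.21, 0.00808) and Wnt targets (-0.11, 0.0237), with adjusted p = 0.423, 0.423, 0.763 and 0.662 with an estimated correlation. Adipocyte genes were higher (median 1.02, 22 of 22 positive, camera adjusted p = 8.16e-12; adjusted p = 0.423 with an estimated correlation), with Slc2a4 at 0.78. So were lists of lipogenesis (0.36, 0.000103) with Fasn at 0.83, lipolysis (0.18, 0.000396) with Pnpla2 at 0.75, oxidative phosphorylation (0.21, 1.63e-07), cell cycle (0.53, 8.05e-05) and macrophages (0.18, 9.89e-05), with adjusted p = 0.423, 0.423, 0.662, 0.485 and 0.763 with an estimated correlation. The cell cycle list leaned on knockout 4, whose mean log2 CPM over the list was 4.10 against 2.90 to 3.13 in the other knockouts and 2.51 to 3.24 in controls (camera adjusted p = 0.0213 without it). The adipocyte transcript Adipoq ranged from 8.96 to 81.1 CPM in SVC controls and from 15.9 to 156 CPM in SVC knockouts, against 4325 to 5570 CPM in male control adipocytes. Of the uncalled lists, the cadherin and catenin list had a median of 0.09 (camera adjusted p = 0.952), with Cdh11 at -1.58, and the stress list 0.02 (0.231), with Hspa1a at -1.91; Mmp12 stood at 1.64 (each adjusted p = 0.968 for the genes). SVC control 1 held epididymal transcripts (Gpx5 1979 CPM, Adam7 934 CPM) and SVC knockout 4 the sperm protamine transcript Prm1 at 326 CPM. Without these 2 libraries 0 genes were called and 374 had an unadjusted p below 0.05. The Wnt target list lost its call without control 1, control 2, knockout 2 or knockout 4 (adjusted p = 0.200, 0.0656, 0.130 and 0.234), the matrix list without control 2, control 3, knockout 3 or knockout 4 (0.128, 0.0718, 0.0830 and 0.573) and the macrophage list without control 1 (0.0969).

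The number of lists called in SVC rose with any 1 library left out, from 12 to between 13 and 18. Lists gained were cholesterol synthesis without control 1 or knockout 2 or 4 (adjusted p = 0.00279, 0.0281 and 0.0227), lymphocyte markers without control 1 or 2 or knockout 2 or 3 (0.000419, 0.00175, 0.0413 and 0.0214) and endothelial markers without control 2 or knockout 4 (0.00723 and 7.43e-06). So were mammary and skin markers without control 2 or knockout 1 or 3 (0.000619, 0.0356 and 0.00899), inflammatory cytokines without control 1, 2 or 3 (0.0432, 0.00108 and 2.84e-05) and the interferon list without control 1 or knockout 1 or 2 (0.000464, 0.000825 and 0.0228). Further ones were stress genes without knockout 1 or 2 (0.0106 and 0.0353), clock genes without control 3 or knockout 2 (0.0210 and 0.0284), erythroid markers without knockout 2 or 3 (0.0295 and 0.00226) and epididymal and testicular markers without control 3 or knockout 4 (0.00982 and 0.0387). The last were granulocyte markers without control 3 (0.00279), mural markers without knockout 1 (0.00812) and sex-linked genes without knockout 2 (0.0413).

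**Figure D4:**
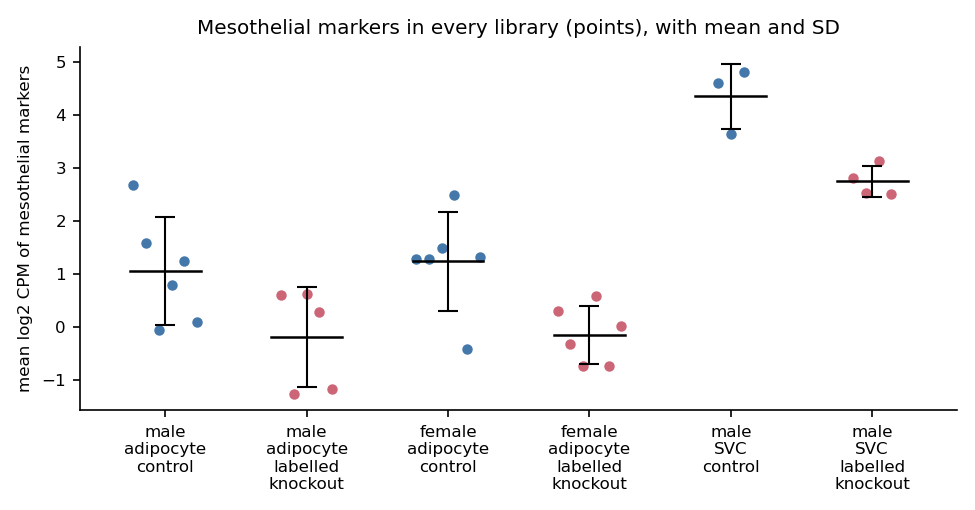
Mean log2 CPM of the mesothelial markers (vertical axis) in each library (points), by group, with the mean and SD of each group. The group means are lower in libraries labelled knockout by 1.24 in male adipocytes, 1.39 in female adipocytes and 1.60 in SVC.

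The knockout effect did not differ detectably between SVC and adipocytes of males: edgeR called 0 of 17251 genes, 1149 had an unadjusted p below 0.05 where 863 are expected, and DESeq2 called 22, limma-voom 0 and edgeR with all 30 libraries 4. In simulated counts edgeR recovered 2.99% of genes changed 1.5-fold, 7.46% of those changed 2-fold and 54.5% of those changed 4-fold in this comparison. The absence of calls therefore does not exclude differences of these sizes. This fit also treated the fractions as independent, though some may come from the same animals. The difference for Ctnnb1 was 0.16 (SE 0.24, adjusted p = 0.894). Leaving out SVC control 2 or SVC control 3 gave 1 called gene each.

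Rpl29, a ribosomal protein gene on chromosome 9, separated most libraries by genotype label in both sexes and both fractions. It lay between 90.2 and 127 CPM in male knockout adipocytes, between 87.9 and 147 CPM in 5 of 6 female knockouts and between 140 and 144 CPM in SVC knockouts, against 19.8 to 33.4 CPM in 11 of 12 adipocyte controls. The exceptions were male control 5 (100 CPM), female knockout 2 (25.8 CPM) and SVC control 3 (168 CPM, the other SVC controls 26.6 and 30.3 CPM). Male control 5 and SVC control 3 carry the same number 5 in the deposited column names. The neighbouring genes Ppm1m and Parp3 followed Rpl29 in adipocytes, with male control 5 at 147 and 122 CPM and female knockout 2 at 42.5 and 86.7 CPM. Rpl29 has many pseudogenes, so its level is uncertain.

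**Figure D5:**
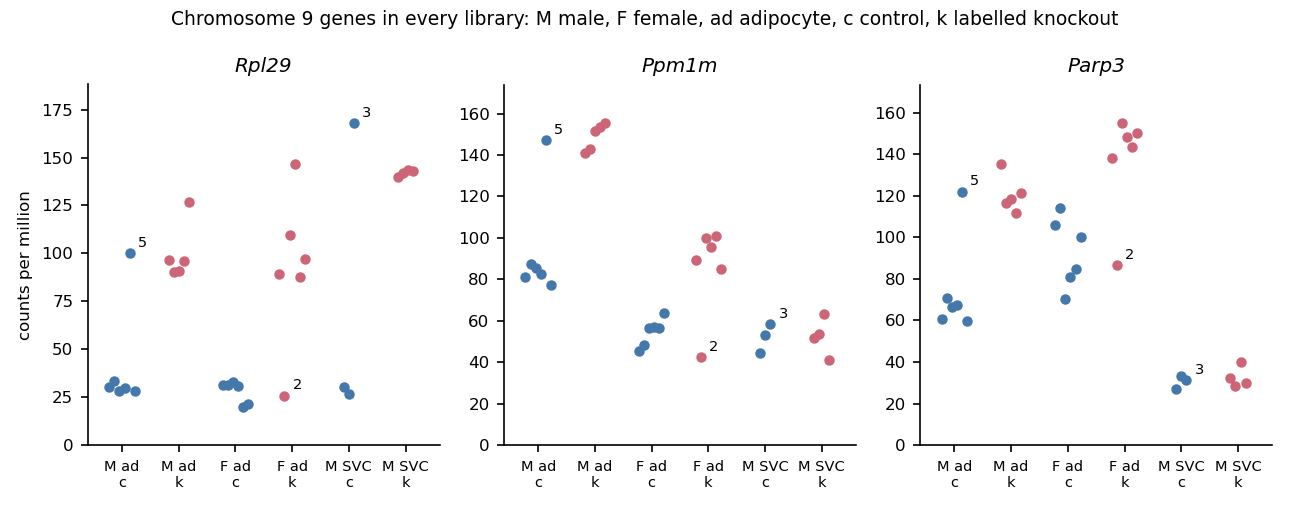
Rpl29, Ppm1m and Parp3 in CPM (vertical axes) in each of the 30 libraries (points), by group, with numbers beside male control 5, female knockout 2 and SVC control 3. These libraries lie at the Rpl29 level of the other label, for example 100 CPM in male control 5 against 28.3 to 33.4 CPM in the other male controls.

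Control adipocytes of females and males differed widely, in genes of body position, the clock, macrophages and stroma. The posterior homeobox genes Hoxa10 and Hoxc10 stood at 21.6 ± 4.72 and 17.6 ± 3.25 CPM in females and at 0.362 ± 0.414 and 0.577 ± 0.246 CPM in males (log2 5.85 and 4.91), while Hoxc4 was lower in females (2.82 ± 0.354 against 14.1 ± 1.83 CPM, log2 -2.32). The clock output gene Dbp was at 20.9 ± 11.7 CPM in females and 215 ± 49.3 CPM in males (log2 -3.37), with Ciart lower (-2.51) and Npas2 higher (4.55). Macrophage genes were lower in females, among them Gpnmb (-3.19), Itgax (-2.98) and Trem2 (-1.79), and progenitor genes higher, among them Pi16 (4.14), Lum (2.33) and Cd55 (1.81), all with adjusted p of 5.71e-05 or less (n = 6 each).

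In all, 6227 of 14227 genes were called, 3373 higher and 2854 lower in females. Of the macrophage markers 12 of 19 were lower (median -0.98, camera adjusted p = 1.61e-05), and of the clock genes 11 were lower and 3 higher (-0.83, 0.00241). Of the preadipocyte markers 10 were higher and 1 lower (0.79, 0.0111), and of the subcutaneous depot markers 4 higher and 1 lower (4.09, 0.0111). With an estimated correlation the values were adjusted p = 0.920, 0.920, 0.920 and 0.418. Grb14 was lower in female controls (6.51 against 26.5 CPM, log2 -2.02, adjusted p = 1.32e-08), as was Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation (log2 -1.48). Of 29 Wnt ligands, receptors and modulators 5 were higher, the inhibitor Sfrp4 among them (3.38), and 5 lower. Of 14 Wnt targets 3 were higher, Nkd1 among them (1.32), and 2 lower. Nrn1 had a log2 fold change of 7.08 (20.2 CPM in females and 0.141 CPM in males). With an index of subcutaneous against visceral markers as a covariate 13 genes were called. The subcutaneous part of this index was at 2.15 to 2.65 in female controls and at -0.73 to 0.47 in male controls. Such a covariate nearly repeats sex, so the fall in calls cannot show that depot accounts for the difference. The labels do not assign depots to libraries, and from them sex, depot and batch cannot be separated.

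Male control adipocytes and SVC differed as fat cells differ from the other cells of the tissue. All 22 adipocyte genes were higher in adipocytes (median log2 6.71), with Cfd at 8.25, Retn at 8.16, Adipoq at 7.53 (5681 ± 536 against 30.7 ± 37.2 CPM), Scd1 at 6.86, the hormone-sensitive lipase gene Lipe at 6.20 and the glycogen synthase gene Gys1 at 5.43. All 25 oxidative phosphorylation genes (median 2.53) and 20 of 25 lipogenesis genes (4.51) were higher. Lower in adipocytes were 17 of 20 preadipocyte markers (median -4.24; Pi16 -9.21, Fbn1 -7.29, Pdgfra -6.94), the matrix gene Fn1 (-5.51), and all 20 macrophage (-2.98), 22 lymphocyte (-6.58), 16 granulocyte (-5.35) and 14 mesothelial markers (-2.99). So were 27 of 36 Wnt ligands, receptors and modulators (-2.43; Sfrp4 -6.75) and the Wnt transcription factors Lef1 (-7.63) and Tcf7 (-6.60).

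The comparison called 13293 of 17251 genes, 5661 higher and 7632 lower in adipocytes (n = 6 and 3), with a median log2 fold change of all genes of -0.29 under TMM and -0.41 under upper-quartile scaling, to which the values above are relative. Camera called 16 lists, 0 with an estimated correlation (lowest adjusted p = 0.0631), and fry 27.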

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

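The tests of single libraries and of differences between the sexes were fixed beforehand. The predictions of the tests over other splits, and of the tests of the chromosome 9 pattern except that of mislabelling, were written only after the results they bear on were seen. Among the named genes, 161 combinations of a gene and a group of 4 or more libraries were examined for 1 library far from the rest; 16 stood out where chance gives 8.

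In male adipocytes, control 2 was far from the other controls in 5 genes: Btbd10 (19.7 CPM), Morf4l2 (187 CPM), Hoxa10 (1.23 CPM), Nrn1 (0.408 CPM) and Cd55 (20.4 CPM), each above the others. Control 6 was high in the macrophage genes Gpnmb (35.7 CPM) and Itgax (10.8 CPM), control 1 in Pdgfra (3.30 CPM), and control 3 was low in Bckdhb (170 CPM). Knockout 5 was high in Bckdhb (194 CPM), nearer the controls. In females, control 4 was high in Igfbp2 (7.32 CPM) and Krt7 (22.2 CPM), control 6 in Ucp1 (72.4 CPM), knockout 3 in Ppargc1a (10.2 CPM) and knockout 4 in Krt7 (1.14 CPM). SVC knockout 1 was high in Igkv8-19 (1.06 CPM).

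The effect of the knockout label differed between the sexes, which cannot be separated from depot or batch, for Serpina3k (log2 difference, female minus male, 2.01) and Akirin2 (-0.57). It also differed by camera for 10 lists: lipogenesis (adjusted p = 5.15e-06), cholesterol (0.0493), Wnt targets (0.0293), lipolysis and fatty acid oxidation (3.50e-05), thermogenic genes (1.96e-06), oxidative phosphorylation (3.99e-06), macrophage markers (1.96e-10), interferon response (5.72e-05), immediate-early stress (0.00171) and unfolded protein response with hypoxia (0.0104). With an estimated correlation none was called (lowest adjusted p = 0.341). Of 100 splits of the libraries, the real one included, 4 gave as many differing genes (real 2, highest other 678). As many lists came from 36 (real 10, highest other 19). The bound was 5%, and the 100 splits are a sample of those possible. For the number of genes, 4 of 100 is below that bound but too near it to exclude chance. For the number of lists chance is not excluded.

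For the genotype effects themselves, 3 of 100 splits, the real one included, gave as many genes in males (real 10, highest other 1292). In females 5 of 100 did (real 67, highest other 2390). Against the bound of 5%, a sample of 100 splits cannot tell these shares apart. Chance is therefore not firmly excluded in males and not excluded in females. Splits that call over 1000 genes point to structure among the libraries other than the genotype label. The number of lists was matched by 98 of 100 splits in males (real 1, highest other 14), 11 of 100 in females (15, 19) and 22 of 35 in SVC (12, 20), and the SVC count of 0 genes by all 35 (highest other 0). The genotype effect differing between fractions (0 genes) was matched by 100 of 100 splits (highest other 1406). Any split matches a count of 0, so these shares for genes in SVC and between fractions could not have come out otherwise. The correlation between the sexes (0.248) was matched by 3 of 100 (highest other 0.302). The counts between sexes (6227) and fractions (13293) were reached by 1 of 100 and 1 of 84 splits, the real ones (highest others 2180 and 0), and their lists (4 and 16) by 76 of 100 (highest other 15) and 31 of 84 (highest other 20).

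A stretch of chromosome 9 stood apart. Averaged over both sexes, 7 of 25 neighbouring tested genes (Glyctk, Ppm1m, Rpl29, Acy1, Abhd14b, Parp3 and Hemk1) had p below 0.001 with 1 sign in both, 5 higher and 2 lower, led by Rpl29 (log2 1.51, SE 0.23, adjusted p = 0.00285); shuffled positions gave as many in 1 of 1000 draws, and 2 of 100 splits of the libraries did (real 7, highest other 8). Its 33 pseudogene copies together lost 9.56% of the CPM that Rpl29 gained, so reads moved from counted copies do not account for most of the gain. In these adipocyte exceptions the copy Gm8210 ran opposite to Rpl29. It was at 5.17 CPM in male control 5 (other male controls 8.04 to 12.2) and 11.8 CPM in female knockout 2 (other female knockouts 4.50 to 5.97). In SVC control 3, with Rpl29 at 168 CPM, Gm8210 did not follow this. It stood there at 7.07 CPM (other SVC controls 6.67 and 7.67, SVC knockouts 3.58 to 5.83). Reads dropped for matching several copies were not seen, so moved reads are not excluded. Male control 5 (100 CPM) and female knockout 2 (25.8 CPM) carry Rpl29 at the level of the other label. They lay nearer that label in at most 38.3% of genes called elsewhere, which argues against wrong labels. In these 2 libraries 10 of 12 values of the other run genes lay nearer the other label, more often than elsewhere (one-sided Fisher's exact p = 0.000574). This p treats neighbouring genes of the same library as independent and overstates the evidence. Each of these libraries had 5 of 6 such genes nearer the other label, and the other adipocyte libraries at most 2. A candidate explanation is a variant on chromosome 9. Where this stretch lies relative to the targeted gene Ctnnb1 was not examined. Without these 2 libraries 81 genes were called over both sexes, and 60 of them lay on other chromosomes. The rest lay on chromosome 9 or had no place in the annotation used. It stays open whether other genes called here follow such a variant and not the loss of β-catenin.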

How the results depend on the processing

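The alternatives were fixed beforehand except the fits that leave out male knockout 5 with female knockout 3, or SVC control 1 with SVC knockout 4, and all settings of the averaged contrast, which were chosen after seeing the data. Where a count changed, the cause was not tested, except that fits of fewer libraries have less power by construction.

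DESeq2 called 159 genes in male adipocytes, 206 in female adipocytes, 76 in SVC, 23 for the difference between sexes, 22 for the difference between fractions and 350 for the averaged contrast. With all 30 libraries in the fit the counts were 2, 19, 19, 0 and 4, and with the 2 groups alone 6 in males and 26 in females. The replicate block by title number gave 4 genes in males, 89 in females (37 of the 67 kept), 1 in SVC and 1 for the difference between sexes. The macrophage index as covariate gave 17 in males, 20 in females and 0 for the difference, the depot index 33 in females, 0 for the difference and 13 between sexes, and the preadipocyte index 89 in males and 3420 between sexes. Without a filter beyond 1 count the difference between sexes had 1. Without male knockout 5 and female knockout 3 the counts were 409 in males, 109 in females, 23 for the difference and 338 averaged, and the male list count was 4.

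With an estimated correlation the called lists numbered 0 in males, 1 in females, 0 in SVC, 0 for the difference, 0 between sexes and 0 between fractions. Fry called 0, 1, 0, 0, 11 and 27.

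Leaving out each library in turn gave 4 to 332 genes in males, 32 to 89 in females, 0 to 1 in SVC, 0 to 22 for the difference between sexes, 0 to 1 for that between fractions, 5548 to 6325 between sexes, 12259 to 13482 between fractions and 60 to 246 averaged. List counts ran from 1 to 4, 13 to 17, 13 to 18, 8 to 11 (difference), 4 to 5 (sexes) and 16 to 16 (fractions). The correlation between sexes ran from 0.133 to 0.302. In SVC 2 uncalled lists turned direction and were called: mural markers without SVC knockout replicate 1 (adjusted p = 0.00812; 0.00812 to 0.727 over all left-out libraries) and inflammatory genes without SVC control replicate 3 (2.84e-05; 2.84e-05 to 0.947). Among named genes 64 values weakened and 22 strengthened in males, 170 and 34 in females, with no reversal.

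Replicate numbers do not state pairs. Female libraries of the same title number correlated at -0.0523 to 0.437 across genes, male adipocyte libraries at -0.148 to 0.0961, and male knockout adipocyte and SVC libraries of the same column-name number at 0.190 to 0.245, a hint from the data of shared animals. In SVC the spread between libraries was larger (common biological coefficient of variation 0.613, against 0.206 in adipocytes). The effects of spread and of library number on the calls there were not separated.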

Other observations

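The average over both sexes and the tests of patterns here were chosen after the patterns were seen, except the test of depot mix. The bounds of that test and of those against the largest of all lists were set before their values were computed. Averaging the genotype effect over both sexes, edgeR called 108 of 14227 genes, 59 higher and 49 lower. Of 100 sampled splits, the real one included, 3 gave as many (highest other 2173). This lies below the bound of 5% but, in a sample of this size, too near it to exclude chance. DESeq2 called 350, and single libraries moved the count: 60 without male control 1, 65 without male control 4, 70, 67 and 68 without male knockouts 1, 2 and 4, 246 without male knockout 5, 68 without female control 3 and 65 without female knockout 1. Grb14 was called in females and had the same sign in males, while Cidea stood at 8.41 CPM in male controls and 8.72 CPM in male knockouts.

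Mesothelial markers were lower in libraries labelled knockout in both sexes and both fractions. The mean index difference of the 2 adipocyte comparisons was -1.32 (permutation p = 0.00167), but this list was chosen among 30 on the same libraries. Against the largest of all 30 lists the permutation p was 0.0656, so chance stays open, and with an estimated correlation the list was not called (adjusted p = 0.932 in males and 0.286 in females). The exact permutation p of the index alone was 0.0758 in males (n = 5 and 6), 0.0152 in females (n = 6 each) and 0.0286 in SVC (n = 4 and 3), the smallest p that SVC can give. Against the mean of 5 other cell type lists the difference was -1.24 (permutation p = 3e-04). This p does not allow for the choice of the list, so it does not settle whether cells that are not adipocytes fell in general. Of these lists, the endothelial and mural indices were not lower in males (0.09 and 0.06) or females (0.06 and 0.02). The preadipocyte index was lower in both (-0.13 and -0.19), and the others differed between the sexes. In all, 12 of 13 measured markers were lower in both sexes, as fewer mesothelial cells would give, and this too stays open.

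In female adipocytes the thermogenic index differed with exact permutation p = 0.00433 and the macrophage index with p = 0.0195 (n = 6 each), again for lists chosen on the same libraries. Against the largest of all 30 lists the exact permutation p was 0.0238 for the thermogenic index and 0.290 for the macrophage index, for which chance stays open. The thermogenic value argues against chance within females, but it does not allow for the choice of females among the genotype comparisons. In males and SVC the thermogenic index alone gave exact permutation p = 0.771 and 0.971. The macrophage index fell by more than the mean of 4 other cell type lists (exact permutation p = 0.0130). This p does not allow for the choice of the list, so it does not settle whether every cell type besides adipocytes was lost. The differences of those lists were 0.06 (endothelial), 0.02 (mural), 0.07 (lymphocyte) and -0.19 (preadipocyte). With an index of subcutaneous against visceral markers as a covariate the thermogenic median was 0.70 (1.07 without it; camera adjusted p = 3.13e-10, and 0.0295 with an estimated correlation), which argues against a shift in depot mix as the whole cause. The number of called members fell from 4 to 1. An effect of the knockout on thermogenic genes in females is 1 hypothesis these values leave open. Food, temperature and housing are not given in the sources used here.

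Genes beside Adipoq were examined because a transgene built from that region could carry neighbours along. The 4 tested genes next to it on 1 side were higher in both sexes: Rfc4 (averaged log2 0.55, SE 0.10, adjusted p = 0.00473), Eif4a2 (0.39, adjusted p = 0.0971), 6330408M09Rik (0.57, adjusted p = 0.0964) and Gm49624 (0.73, adjusted p = 0.0913). The next gene on that side, Kng2, was at 0.23 (adjusted p = 0.740). The other side did not move together: St6gal1 was at -0.19, Masp1 at -0.60, Gm45338 at -0.62, Rtp4 at 0.66 and Bcl6 at -0.01 (adjusted p = 0.420, 0.513, 0.533, 0.144 and 0.983). Adipoq itself was at -0.12 (adjusted p = 0.567). With an unadjusted p below 0.001 there was 1 of 10 neighbours, and 6.15% of 14025 tested genes have as many. This count leaves out the genes just short of that p, so extra copies of the region stay open.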
